A study of Mus musculus with 6 samples.

How the data were processed

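Messenger RNA levels were measured on 6 single-colour Affymetrix mouse arrays, 2 arrays in each of 3 groups. Ovarian surface epithelial cells from tumours were digested with trypsin, plated and collected without passage, per the labels. The groups differ in p53 status: wild-type, heterozygous for the p53 R172H mutation, or homozygous for it. Part of the sample labels is not reported here. One label field of the homozygous samples names a related gene in place of p53, and the sample titles were followed. Both wild-type animals were 9 weeks old, the heterozygous animals 9 and 12 weeks, and both homozygous animals 4 weeks, so age could not be separated from homozygosity.

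The deposited values are probe set intensities, from total RNA labelled with biotin by the standard Affymetrix procedure per the labels. The submitters' processing notes name RMA, whose version is not given in the sources used here. The values themselves are linear intensities for 45101 probe sets with different quantiles in each array, and the mean over the middle 96% of probe sets is 500 in every array, which is the form of MAS 5.0 signals rather than of RMA output. The design had assumed RMA values, with log2 to be taken of deposited values above 30; this applied, and log2 was taken of the deposited intensities with no offset. No background filter or normalisation was added. Linear signals of this kind spread widely near background on the log2 scale, so folds of dim genes are uncertain. The highest of 18 values of the bacterial Trpn control probe sets, 24.5, served as the background level. A fold against a group in which both arrays lay under this level is given as a lower bound computed against it. Array data have no count depth, and the number of arrays limits the precision.

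Probe sets were named from the platform annotation supplied with the values, with symbols updated by Entrez identifier through a mouse RefSeq gene table. Of the 45101 probe sets, 34958 named 1 gene symbol, 932 named several and 9211 named none. Those with several or none were not used, and 34754 of the single-symbol probe sets were matched by identifier. The transcript of the mutated gene was absent from the names and was not analysed. Each of 18194 genes was represented by its probe set with the highest mean, a choice that mattered for 9012 genes with several probe sets. Genes whose mean was at or above the 40th percentile, a geometric mean signal of at least 60.3, were tested, which left 10916.

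Linear models were fitted with limma 3.58.1 in R 4.3.3, with 3 group means in a single fit of all 6 arrays, no covariate and empirical Bayes moderation. The fit has 3 residual degrees of freedom and 2.26 prior degrees of freedom. The contrasts were heterozygous minus wild-type, homozygous minus wild-type, homozygous minus heterozygous, and heterozygous minus the midpoint of the other 2 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors beside log2 fold changes are limma standard errors. Fixed gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 30 lists that had at least 5 tested members. The same test with an estimated correlation and limma's fry, which asks whether the genes of a list move on balance one way, were run beside it. With an estimated correlation, camera also refers its statistic to the 3 residual degrees of freedom, which makes it much harder to pass. A list that fails it is therefore not shown to owe its call to correlation between its genes.

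The samples' groups, the test, the filter, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names, in each comparison of 2 groups, the 12 called genes with the largest rise and the 12 with the largest fall whose arrays do not overlap, filled to 5 by the smallest p where fewer than 5 pass. It also allows up to 3 members to be named from each list that passes or holds a called gene, up to 6 p53 targets in every comparison, and the genes called against the midpoint. Genes named beyond this rule are said to be so. The signal pattern in each array and the figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

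The procedure was tested on simulated data with the fitted spread and 200 genes shifted in each comparison. For homozygous against wild-type arrays, 0% of genes shifted by 1 on the log2 scale were recovered, 35.8% of those shifted by 2 and 90.9% of those shifted by 4, with 3 unshifted genes among 87 calls. For heterozygous against wild-type arrays the shares were 0%, 43.3% and 78.8%, with 3 unshifted genes among 84 calls. For homozygous against heterozygous arrays they were 2.99%, 40.3% and 87.9%, with 4 among 91. In each of these simulations a list of 30 genes shifted by 1 was called and 0 of 30 unshifted lists were. The simulated genes varied independently of each other, with the same spread in all groups. The simulations therefore do not test false calls of lists whose genes vary together. Real groups differed in spread, so the shares recovered are not those of the real comparisons.

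The alternatives were an intensity trend with robust moderation, no filter or a filter at the 60th percentile, the mean of all probe sets, every probe set tested singly, median-centred or quantile-normalised arrays, a fit of only the 2 groups compared, the replicate number as a block, each array left out in turn, an adjusted p under 0.10, a minimum fold, and the other list tests. Added after the data had been seen were an offset of 32 before log2, signals raised to the background level, crossed replicate numbers, leaving out 2 arrays that lay close together across groups, and a spread that differs between groups.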

Results

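Gene expression was compared in cultured tumour cells of the mouse ovarian surface epithelium, the single cell layer that covers the ovary, with wild-type p53, with the R172H mutation on 1 of the alleles (heterozygous), or with R172H on both (homozygous). The question stated for the series is how expression differs with the status of p53, a transcription factor that stops the cell cycle or triggers cell death after damage. Each group held 2 arrays with 45101 probe sets, and the median signal of an array lay between 41.1 and 60.6 against a background level of 24.5. Homozygous cells came from animals of 4 weeks and the others from animals of 9 or 12 weeks, so every difference between the homozygous and the other cells is also a difference in age.

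The homozygous arrays stood apart from the other 4 and from each other. On the first principal component, with 72.0% of the variance, homozygous array 1 lay at 135 and homozygous array 2 at 40.3, while the wild-type and heterozygous arrays lay between -54.2 and -35.7. The SD of the log2 difference between the arrays of a pair was 1.30 in the homozygous group, 0.60 in the wild-type and 0.55 in the heterozygous group, and the homozygous pair supplied 72.6% of the pooled spread. The smallest SD of all 15 pairs, 0.31, was that of wild-type array 2 and heterozygous array 1. As signs of RNA quality, the 3' to 5' log2 difference of the beta-actin control was 0.59 and 0.39 in the homozygous arrays and between 0.66 and 0.96 in the others. That of Gapdh lay between -0.18 and 0.01 in all 6. The 5' control of 18S ribosomal RNA had a signal of 6696 in homozygous array 2 and between 16873 and 22559 in the others.

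Homozygous against wild-type cells. Cells homozygous for R172H had far lower signals of several p53 target genes. Cdkn1a, which encodes the cell cycle inhibitor p21, had a signal of 2582 in wild-type and 146 in homozygous cells and fell by 4.14 ± 0.32 (SE) on the log2 scale. Cdkn2a, which encodes the tumour suppressors p16Ink4a and p19Arf, rose from 389 to 7441, by 4.26 ± 0.50. By camera, markers of the surface epithelium, of epithelial junctions and of macrophages lay lower as groups and genes of mitosis and DNA replication higher, the last 2 with 0 of 31 and 0 of 29 genes called. None of these lists passed with an estimated correlation (adjusted p = 0.5005, 0.455, 0.455, 0.576 and 0.576). In total 291 of 10916 tested genes were called by limma, 45 higher and 246 lower, each by at least 2-fold (n = 2 arrays per group).

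Of 39 tested p53 target genes, 7 fell, 0 rose and 32 did not pass, and the list had a median log2 fold change of -0.62. Adjusted over the list alone, 13 fell and 1 rose. Eda2r, a receptor of the tumour necrosis factor family, was at least 18.4-fold lower, since both homozygous arrays lay under background. Fas, the death receptor, fell by 3.28 ± 0.41, or -2.75 with signals raised to background, 1 of its 2 homozygous arrays lying under it. Ddit4l fell by 3.67 ± 0.45 and Ddit4, an inhibitor of mTOR signalling, fell by 3.16 ± 0.43. Ccng1, cyclin G1, fell by 1.64 ± 0.23, and Cd82, a tetraspanin chosen after its values were seen, fell by 1.55 ± 0.23. Mdm2, the ubiquitin ligase that degrades p53 and a member of this list, had signals of 1192 and 943 in wild-type and of 1136 and 1253 in homozygous arrays, and did not pass; it was chosen after its values were seen. The list passed limma's camera with an adjusted p of 0.00598, and had an adjusted p = 0.455 with an estimated correlation. By fry its adjusted p was 0.00593. The median was -0.22 with the filter at the 60th percentile and -0.31 with median-centred arrays, and the list passed in both. Without both wild-type array 2 and heterozygous array 1, which lay close together, it was -0.33 and the call ended (adjusted p 0.0844).

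**Figure D1:**
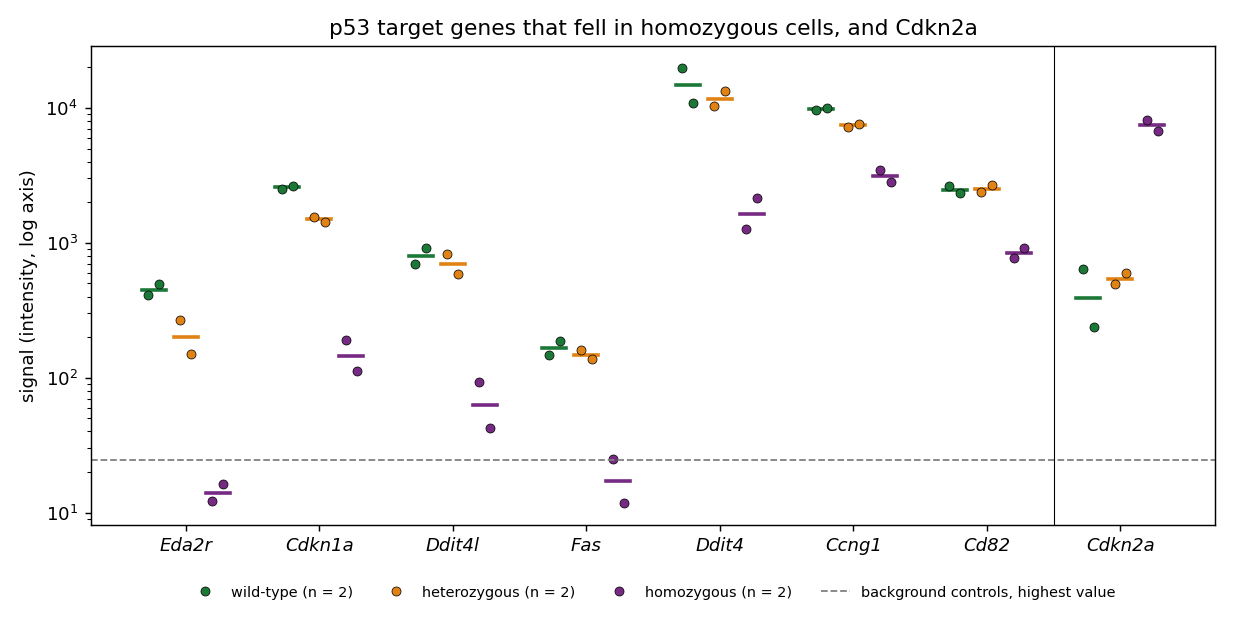
Signal of each array (points, logarithmic axis) and geometric mean of each group (bars, n = 2 arrays) for the 7 p53 target genes that fell in homozygous against wild-type cells and, right of the vertical line, Cdkn2a; the dashed line is the background level of 24.5. The 2 homozygous Cdkn1a values, 192 and 111, lie under the heterozygous values of 1548 and 1437 and the wild-type values of 2519 and 2646.

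All 31 tested genes of G2/M and mitosis had positive fold changes, with a median of 1.42, but 0 passed singly. Top2a, the topoisomerase of replicating cells, had a signal of 3381 in wild-type and 13214 in homozygous cells, and Aurka, a mitotic kinase, 962 and 3204. The 29 genes of DNA replication (median 1.23) and the 25 of DNA repair (median 0.95) were likewise all positive, with 0 calls and 0 adjusted over the list alone, Mcm10 having signals of 304 and 1356 and Fanca 216 and 603. Each of these lists passed camera with an adjusted p of 1.22e-06, and each had an adjusted p = 0.576 with an estimated correlation. By fry the adjusted p were 0.321, 0.264 and 0.159. The mitosis median was 0.70 without wild-type array 1 and 2.24 without wild-type array 2, and the replication median 0.78 without wild-type array 1. Genes of the mitosis list were estimated to correlate at 0.942. They also differed between arrays of a group, with Mki67, the proliferation marker, at 1246 and 4031 in the wild-type arrays, a gene chosen after its values were seen.

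Markers of the ovarian surface epithelium and mesothelium had a median of -2.42, with 22 of 23 negative. The called member Upk1b, a uroplakin, fell by 2.42 ± 0.27, and 13 members fell when adjusted over the list alone. Epithelial junction and keratin genes had a median of -1.60 (-1.34 with signals raised to background), with 2 of 15 called and 7 lower adjusted over the list alone. Epcam, the epithelial adhesion molecule, fell by 5.38 ± 0.39 (-5.31 with signals raised to background, 1 of 2 homozygous arrays lying under it) and Spint1 fell by 2.68 ± 0.38. Camera gave an adjusted p of 2.27e-06 for the first list (adjusted p = 0.5005 with an estimated correlation) and of 0.0149 for the second (adjusted p = 0.455 with an estimated correlation), and fry 0.0450 and 0.0151. The call of the junction list ended with the filter at the 60th percentile (median -0.12, adjusted p 0.519) and without both close arrays (-1.57, adjusted p 0.0676), and its median was -0.75 with no filter. The surface epithelium markers differed between the homozygous arrays as well, with a median of 2.01 on the log2 scale for array 2 minus array 1. Aldh1a2, which makes retinoic acid and had signals of 17461 and 18974 in wild-type arrays, was at 1.1 in homozygous array 1 and 1979 in array 2; it was chosen after its values were seen.

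Markers of other cell types moved with these groups. Of 11 tested macrophage genes 4 fell, and 6 adjusted over the list alone, with a median of -2.04, or -2.09 with signals raised to background. Lyz2, lysozyme of myeloid cells, was at least 24.1-fold lower, and Lyz1, a near-identical paralog whose probe sets do not separate the 2 with certainty, at least 51.2-fold, with 2 of 3 probe sets lower. Mpeg1, a pore-forming macrophage protein, fell by 2.63 ± 0.29 (-2.46 with signals raised to background, 1 of 2 homozygous arrays lying under it). Ctss, cathepsin S, which was chosen after its values were seen, fell from 560 in wild-type cells to 9.00, under background. Of 8 endothelial genes (median -1.71) 3 fell, and 4 adjusted over the list alone: Icam2 was at least 38.7-fold lower, Kdr, a receptor for vascular endothelial growth factor, fell by 5.22 ± 0.46 and Esam fell by 1.83 ± 0.28. Granulosa and theca cell genes had a median of -2.07 (-1.97 with signals raised to background), with 0 of 10 called and 6 lower adjusted over the list alone. The adjusted p by camera was 0.000154 for macrophages (adjusted p = 0.455 with an estimated correlation), 0.00272 for endothelium (adjusted p = 0.466 with an estimated correlation) and 0.00996 for granulosa and theca genes (adjusted p = 0.576 with an estimated correlation). By fry they were 0.0139, 0.0162 and 0.174. The granulosa call ended without homozygous array 1 (median -0.98, adjusted p 0.104), and its median was -3.77 without array 2. The endothelial call ended with no filter (median -0.66), and its median was -1.08 without homozygous array 1. Too few members of 4 further lists were tested: 1 of oocytes, 2 of lymphocytes, 1 of adipocytes and 0 of red blood cells. All their tested members are given here, outside the rule for named genes. Gdf9 had signals of 85.3 and 89.3 in wild-type and 61.2 and 48.2 in homozygous arrays, Zap70 286 and 237 against 221 and 226, Ighm 131 and 159 against 213 and 154, and Lpl 11662 and 5499 against 7734 and 22580.

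Antigen presentation genes were negative in 13 of 13 cases (median -1.44), and H2-K1, a class I heavy chain whose probe sets may also detect its paralogs, fell by 1.67 ± 0.23. In glycolysis and hypoxia 3 of 24 fell (median -0.72): Ndrg1 fell by 4.40 ± 0.31, Car9, a carbonic anhydrase induced by low oxygen, fell by 6.07 ± 0.54 and Bnip3 fell by 1.64 ± 0.24. Cholesterol synthesis genes were negative in 19 of 20 cases (median -0.69), with a called member, Dhcr7, the last reductase of the pathway, that fell by 1.91 ± 0.29. WNT targets had a median of -1.57, and Sp5, with 1 of 2 homozygous arrays under background, fell by 4.57 ± 0.36. Adjusted over the list alone, 7, 5 and 3 genes fell in the first 3 of these lists, and 3 fell and 1 rose among WNT targets. With signals raised to background the antigen presentation median was -1.52 and the WNT median -1.66. Camera gave adjusted p of 0.000744, 0.00963, 0.00598 and 0.0384 for these 4 lists in this order. With an estimated correlation the adjusted p were 0.466, 0.455, 0.576 and 0.576, and by fry 0.0414, 0.0162, 0.144 and 0.116. Without homozygous array 2 the camera calls of the hypoxia list (median -0.51) and the cholesterol list (median -0.26) ended, and without wild-type array 1 (median -1.18) or homozygous array 1 (median -0.84) that of the WNT targets. That last call also ended with no filter (median -0.99), with the filter at the 60th percentile (-0.42), with the mean of all probe sets (-0.95) and with only the 2 groups compared (-1.57).

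RAS-MAPK targets had a median of 0.61, and 2 of 24 rose, Dusp4, a phosphatase that inactivates MAP kinases, by 2.08 ± 0.28 and Spry1, a feedback inhibitor of the pathway, by 2.13 ± 0.32; adjusted over the list alone 3 rose. Ribosomal protein genes had a median of 0.20 with 0 of 18 called. Their adjusted p by camera were 0.0468 and 0.0333 (adjusted p = 0.576 and adjusted p = 0.670 with an estimated correlation), and by fry 0.227 and 0.321. Both camera calls ended with quantile-normalised arrays, with the filter at the 60th percentile, with the mean of all probe sets and with only the 2 groups compared, and that of the RAS-MAPK list also with median-centred arrays. Both ended without wild-type array 1 (medians 0.40 and 0.02), homozygous array 1 (0.05 and 0.14) or heterozygous array 2 (0.61 and 0.17); without wild-type array 2 the ribosomal median was 0.37. The call of the RAS-MAPK list also ended without heterozygous array 1 (0.61). In lists that did not pass, Mthfd2, a mitochondrial folate enzyme among the ATF4 targets, rose by 1.87 ± 0.27, Ltbp2 of the TGF-beta list fell by 3.06 ± 0.39, and Ndn of the imprinted genes fell by 7.14 ± 0.45; with signals raised to background the values were -2.94 for Ltbp2 and -7.09 for Ndn, each with 1 of 2 homozygous arrays under it. The other lists did not pass: mesenchymal genes (median 0.06, mean -0.41), extracellular matrix (-0.10, tested as up), Mullerian markers (-1.86), smooth muscle (-0.41), interferon response (0.30, mean -0.26), cytokines (-0.02, tested as up), PI3K and FOXO targets (-0.52), TGF-beta and BMP targets (0.13, with a mean just under 0), oxidative phosphorylation (0.03), NRF2 and glutathione (-0.43), unfolded protein response (0.05), heat shock genes (-0.32), senescence (0.29), stem cell markers (0.44) and imprinted genes (-0.63). Of these some passed with an array left out. Without homozygous array 1 mesenchymal genes (0.80), extracellular matrix (0.44), interferon genes (1.69) and NRF2 genes (-0.76) did. Without homozygous array 2 smooth muscle (-1.51), Mullerian markers (-2.22), extracellular matrix (-1.47) and interferon genes (-1.49) did, and without wild-type array 1 NRF2 genes (-0.71).

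Among single genes the largest rise was that of Foxa2, a forkhead transcription factor, which was at least 57.5-fold higher. It was followed, after Cdkn2a, by Nr2f1 (log2 3.46 ± 0.50), Sgk1, a kinase downstream of PI3K signalling (3.28 ± 0.50), and Aif1l (3.06 ± 0.27). Pdzrn3 and Antxr1 rose by 3.11 and 2.58, each with only 1 of 2 probe sets higher. Sh3kbp1, Fam107b, Niban2, Vash2 and Ddr2, a collagen receptor, rose by between 2.64 and 2.77. Among the falls with the largest fitted values, whose order is uncertain under background, were, beside Lyz1 and Icam2, those of Hsd17b2, which inactivates oestradiol (at least 77.4-fold), Aard (64.8-fold), Tnfsf13os (38.6-fold, 1 of 2 probe sets), Pla2g5 (32.7-fold), Hdc, which makes histamine (23.1-fold), Srgn (19.7-fold) and Mybpc2 (14.9-fold), each a lower bound. Kctd14 fell by 6.84. Smim22, with homozygous signals of 26.4 and 6.4, the second under background, fell by 7.40, or -6.43 with signals raised to background.

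These calls stand close to the threshold, the smallest adjusted p being 0.0110 by limma. The errors come from a spread pooled over the 3 groups. The mean variance within the pair was 0.877 in the homozygous, 0.178 in the wild-type and 0.154 in the heterozygous group. The pooled errors are therefore likely too small for both comparisons with homozygous cells. With a spread differing between groups 194 genes were called against wild-type cells. Leaving out either wild-type or either heterozygous array, or using only the 2 groups compared, no filter on dim genes or the replicate block, gave 0 calls, whereas leaving out homozygous array 1 gave 729 and leaving out array 2 gave 2720. Arrays did not overlap for 61.2% of genes, against 33.3% by chance. The median of all genes was -0.09, and centring the arrays on their medians moved it to 0.22 and reversed the direction of none of the gene lists and named genes that passed.

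**Figure D2:**
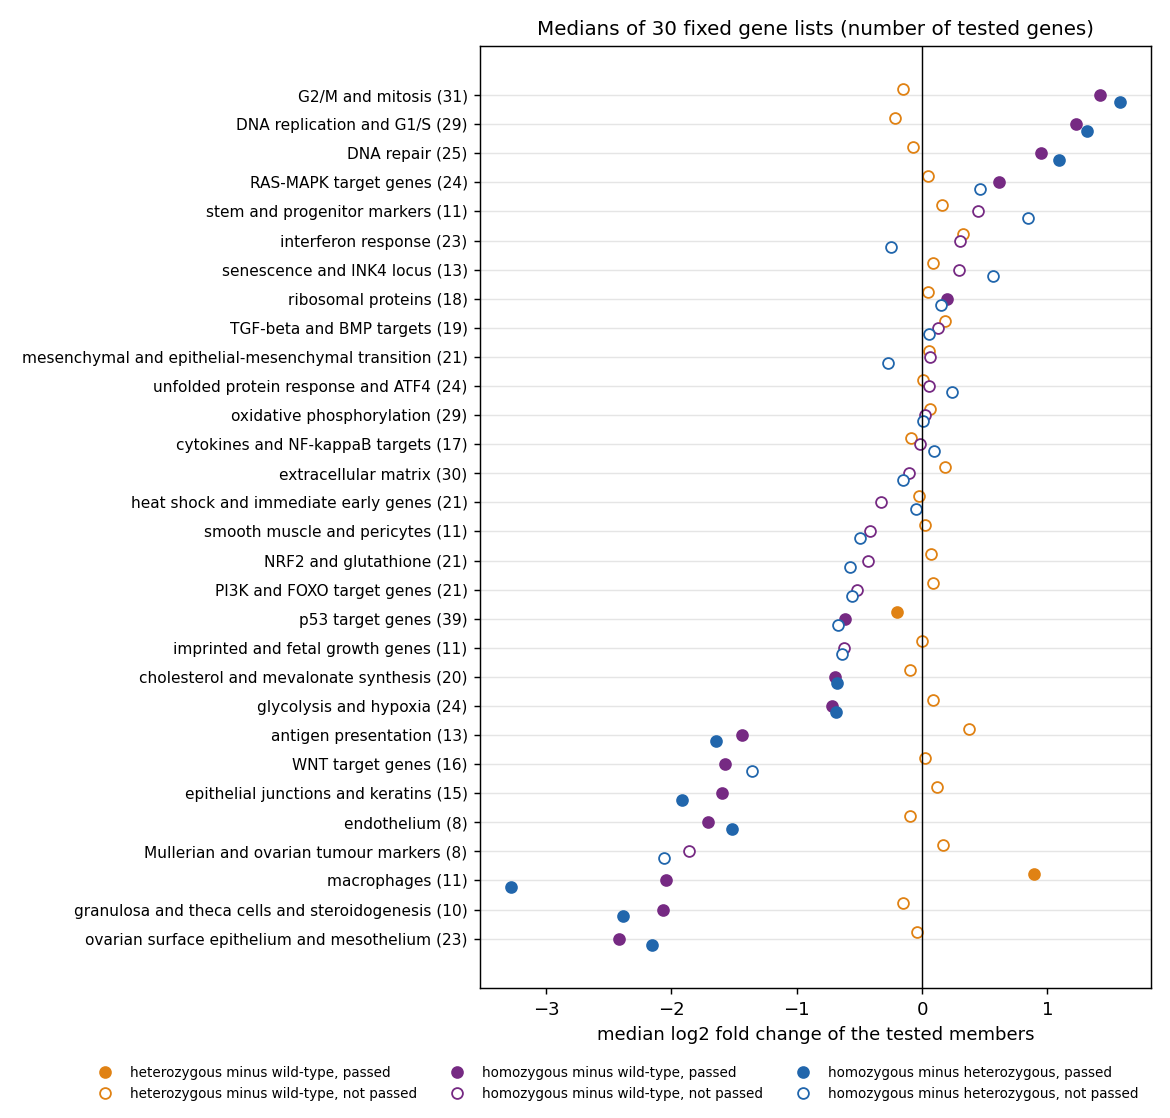
Median log2 fold change of the tested members (horizontal axis) of 30 fixed gene lists in 3 comparisons; filled points passed limma's camera at a preset correlation, open points did not, and no list passed with an estimated correlation. Homozygous minus wild-type medians run from -2.42 for the surface epithelium to 1.42 for mitosis.

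Homozygous against heterozygous cells. Compared with the heterozygous cells, which keep a wild-type allele, the homozygous cells again had low Cdkn1a, which fell by 3.35 ± 0.32 on the log2 scale from a signal of 1491. Cdkn2a rose by 3.78 ± 0.50. Macrophage genes had a median of -3.28 (adjusted p = 0.475 with an estimated correlation), further from 0 than against wild-type cells, and Epcam, a junction gene, fell by 4.94 ± 0.39. Limma called 446 genes, 95 higher and 351 lower, all by at least 2-fold (n = 2 arrays per group).

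Of 39 p53 targets 7 fell and 0 rose, and 13 fell and 1 rose adjusted over the list alone. Eda2r was at least 8.18-fold lower, Ddit4l fell by 3.48 ± 0.45, Fas fell by 3.11 ± 0.41 (-2.58 with signals raised to background), Ddit4 fell by 2.83 ± 0.43, Cd82 fell by 1.58 ± 0.23 with 1 of 2 probe sets lower, and Sesn1, a sestrin that the FOXO list also holds, fell by 1.67 ± 0.27 with 3 of 4 probe sets lower. The list did not pass camera (median -0.67, adjusted p 0.0542, and adjusted p = 0.484 with an estimated correlation); by fry its adjusted p was 0.00764. It passed camera without heterozygous array 2 (median -0.50) and without homozygous array 1 (median -0.43). All 31 mitosis genes were positive (median 1.58), with 0 called. All 29 replication genes were positive as well (median 1.31), and Ccne1, cyclin E1, rose by 1.24 ± 0.22. The 25 repair genes had a median of 1.09, with 0 called. Camera gave adjusted p of 2.86e-07, 1.53e-07 and 1.80e-06 for the 3 lists, and each had an adjusted p = 0.634 with an estimated correlation. By fry the adjusted p were 0.272, 0.197 and 0.142. Without heterozygous array 1 the mitosis and replication medians were 2.48 and 2.02, and without heterozygous array 2 the medians of the 3 lists were 0.77, 0.78 and 0.69. The repair median was also 0.69 with the filter at the 60th percentile.

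In the surface epithelium list 2 of 23 fell and 13 adjusted over the list alone (median -2.15): Upk1b fell by 2.05 ± 0.27 and Crip1 fell by 2.97 ± 0.51. Of 15 junction genes 4 fell and 7 adjusted over the list alone (median -1.92, or -1.66 with signals raised to background): Dsc2, a desmosomal cadherin, fell by 1.92 ± 0.26, Ocln, occludin, which was chosen after its values were seen, fell by 4.02 ± 0.57, and Spint1 fell by 3.25 ± 0.38 beside Epcam. Of 11 macrophage genes 5 fell and 8 adjusted over the list alone, Lyz2 being at least 44.6-fold and Ctss at least 50.8-fold lower, while Mpeg1 fell by 3.28 ± 0.29 (-3.12 with signals raised to background) and Fcer1g, chosen after its values were seen, fell by 2.48 ± 0.38; with signals raised to background the median was -2.96. Endothelial genes had a median of -1.51 with the same 3 members called as against wild-type cells, Icam2 with both homozygous arrays under background, while Kdr fell by 4.78 ± 0.46 and Esam fell by 1.77 ± 0.28. Fst, follistatin, of the granulosa list fell by 2.25 ± 0.37 (list median -2.39). Camera gave adjusted p of 7.17e-06, 0.00777, 7.17e-06, 0.00568 and 0.0257 for these 5 lists. With an estimated correlation the adjusted p were 0.548, 0.475, 0.475, 0.546 and 0.634, and by fry 0.0593, 0.0167, 0.00764, 0.0189 and 0.194. The granulosa call ended without homozygous array 1 (median -0.78) and with the filter at the 60th percentile (-2.08). With that filter the junction call ended too (-0.15), as it did without both close arrays (-1.18), and with no filter the endothelial call (-0.74). With no filter the granulosa median was -1.07 and the junction median -1.175. Without homozygous array 1 the junction median was -0.996 and the endothelial median -0.95.

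H2-K1 fell by 2.19 ± 0.23 and Tapbp, which loads peptides onto class I molecules, fell by 1.64 ± 0.29 in the antigen presentation list (median -1.64), where 10 fell adjusted over the list alone. Ndrg1 fell from a signal of 10936 to 594, Car9 fell by 7.10 ± 0.54 and Bnip3 fell by 1.58 ± 0.24 in the hypoxia list (median -0.69), and Dhcr7 fell by 1.81 ± 0.29 in the cholesterol list (median -0.68). These lists passed camera with adjusted p of 8.19e-05, 0.00568 and 0.0257. With an estimated correlation the adjusted p were 0.484, 0.475 and 0.634, and by fry 0.0212, 0.0189 and 0.157. Without homozygous array 2 the hypoxia call (median -0.50) and the cholesterol call (median -0.40) ended, the latter also without heterozygous array 1 (median -0.61) and with median-centred arrays (median -0.45). The RAS-MAPK (median 0.46), WNT (-1.36), NRF2 (-0.58) and Mullerian (-2.06) lists did not pass, with adjusted p of 0.0542 for the first 3 and 0.0757 for the last, but each passed when either wild-type array was left out, with medians then between -2.06 and 0.46. They also passed without homozygous array 2 for RAS-MAPK (0.59), WNT (-2.105) and Mullerian genes (-2.39), without homozygous array 1 for NRF2 (-0.88), without heterozygous array 1 for RAS-MAPK (0.63) and NRF2 (-0.71), and without heterozygous array 2 for WNT (-1.41). Mesenchymal genes passed without homozygous array 1 (0.54) and extracellular matrix without array 2 (-1.82). Among their members and those of other lists that did not pass, Dusp4 rose by 1.90 ± 0.28, Phlda1 by 1.41 ± 0.25 and the chemokine Cxcl12 by 3.60 ± 0.59, the last with 2 of 3 probe sets higher. Jun fell by 2.18 ± 0.36, Sp5 fell by 4.57 ± 0.36, Ltbp2 fell by 4.21 ± 0.39 and Ndn fell by 6.56 ± 0.45 with 6 of 8 probe sets lower, these 3 with 1 of 2 homozygous arrays under background (-4.56, -4.09 and -6.51 with signals raised to it). Median, mean and test differed in sign for the mesenchymal list (median -0.27, tested as up), cytokines (median 0.10, mean -0.15), heat shock genes (median -0.05, tested as up), and, close to 0, the TGF-beta and oxidative phosphorylation lists. Other large rises were those of Tbx20, a cardiac T-box factor (at least 28.2-fold), Foxa2 (5.65 ± 0.71, or 5.58 with signals raised to background), Pdzrn3 (3.98, 1 of 2 probe sets), Cyp1b1 (3.47), Ptger4 (3.36), Gpr85 (3.31, or 3.12 with raised signals, 3 of 4 probe sets), Nr2f1 (3.24), Sgk1 (3.05), Aif1l (2.91) and Sh3kbp1 (2.75). Falls given as lower bounds were those of Hsd17b2 (at least 134-fold), Lyz1 (99.1-fold, 2 of 3 probe sets), Srgn (53.4-fold), Pla2g5 (48.6-fold), Fut2 (44.3-fold), Aard (37.0-fold), Ndufa4l2 (31.5-fold) and Mybpc2 (27.7-fold), while Smim22 fell by 7.88 (-6.91 with signals raised to background) with 1 of 2 probe sets lower.

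The calls of both homozygous comparisons shared 264 genes, all with the same sign, 37 higher and 227 lower, against 0.392 and 7.91 for independent lists of these sizes. Both comparisons use the same homozygous arrays, so their lists are not independent. Leaving out either wild-type array gave 7 calls and leaving out either heterozygous array 0, while leaving out homozygous array 1 or 2 gave 812 or 2913. The count was 17 with no filter, 4 with only the 2 groups compared, 19 with the replicate block and 0 without both close arrays. Arrays did not overlap for 62.5% of genes, against 33.3% by chance. The median of all genes was -0.08, and centring the arrays on their medians moved it to 0.14.

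Heterozygous against wild-type cells. No gene was called between heterozygous and wild-type cells by limma, with 0 of 10916 called and 71 at an unadjusted p under 0.05, 33 higher and 38 lower (n = 2 arrays per group). If no gene had changed, a share of 0.05 would lie under that value, far more than 71, so the test looks overly cautious here. The number was 194 with only the 2 groups compared and 181 with a spread differing between groups. The 0 calls therefore do not show that the groups are alike. By camera 2 lists passed, p53 targets with lower and macrophage genes with higher values, but neither did with an estimated correlation (adjusted p = 0.292 for each) or by fry (0.626 and 0.781). Cdkn1a had signals of 2519 and 2646 in wild-type and of 1548 and 1437 in heterozygous arrays, a log2 difference of -0.79 ± 0.32 that did not pass. The errors in this comparison come from the spread pooled over all 3 groups. Across genes, the homozygous pair, which lies outside the comparison, supplied 72.6% of that spread.

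Of 39 p53 targets 30 had negative values, with a median of -0.20, and 0 passed, also when adjusted over the list alone. Beside Cdkn1a the members with the smallest p were Eda2r (-1.17 ± 0.37), Bbc3, which encodes the pro-apoptotic protein Puma (-0.59 ± 0.30), Ccng1 (-0.40 ± 0.23), Aen (-0.36 ± 0.24) and Ddb2 (0.51 ± 0.32), none of which passed. All 11 macrophage genes had positive values, with a median of 0.89 and 0 called, among them Cd68 (1.71 ± 0.74), Fcer1g (0.87 ± 0.38) and Mpeg1 (0.65 ± 0.29). Of 18 list members above background in both wild-type arrays, tested or not, 10 had both heterozygous arrays above both wild-type arrays. By camera the adjusted p were 0.00142 for p53 targets and 8.65e-06 for macrophage genes, and each had an adjusted p = 0.292 with an estimated correlation. The macrophage median was 0.46 without heterozygous array 1. The camera call of the p53 targets ended with no filter (adjusted p 0.131), without wild-type array 2 (adjusted p 0.308, median -0.16) and without both close arrays (adjusted p 0.321, median -0.21).

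The other 28 lists did not pass, with medians between -0.22 for DNA replication and 0.38 for antigen presentation. Antigen presentation passed without wild-type array 2 (0.58) and without heterozygous array 2 (0.44), and so did interferon genes (0.51 and 0.36), which also passed without homozygous array 1 (0.33) or 2 (0.32). Mullerian markers passed without wild-type array 1 (0.37), where mitosis (-0.94), replication (-0.68) and repair (-0.27) did too. Median, mean and test differed in sign for smooth muscle (median 0.02, tested as down), cytokines (-0.09, tested as up), WNT targets (0.03, tested as down), RAS-MAPK targets (0.05, mean -0.04) and NRF2 genes (0.07, mean -0.03), and the unfolded protein list was tested as down with a median of 0.01. The mitosis median of -0.15 became 0.62 without wild-type array 2 and 0.71 without heterozygous array 2. Genes filled in by the smallest p were Lce1h (1.80 ± 0.33), Trpm6 (1.07 ± 0.27), Il3ra (1.05 ± 0.32), Large2 (0.85 ± 0.23) and Rhpn2 (0.73 ± 0.22) on the higher side. Those on the lower side were Rasd2 (-1.86 ± 0.31), Adgrb2 (-1.02 ± 0.22), Tubb4a (-0.98 ± 0.27), Ranbp6 (-0.93 ± 0.27) and Espn (-0.92 ± 0.23). Arrays did not overlap for 2838 of 10916 genes, a smaller share than the 33.3% given by chance. The simulated test recovered 43.3% of genes shifted by 2 on the log2 scale and 0% of those shifted by 1. It gave these groups the pooled spread, which is wider than their own, so these shares do not measure the sensitivity of the real comparison.

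**Figure D3:**
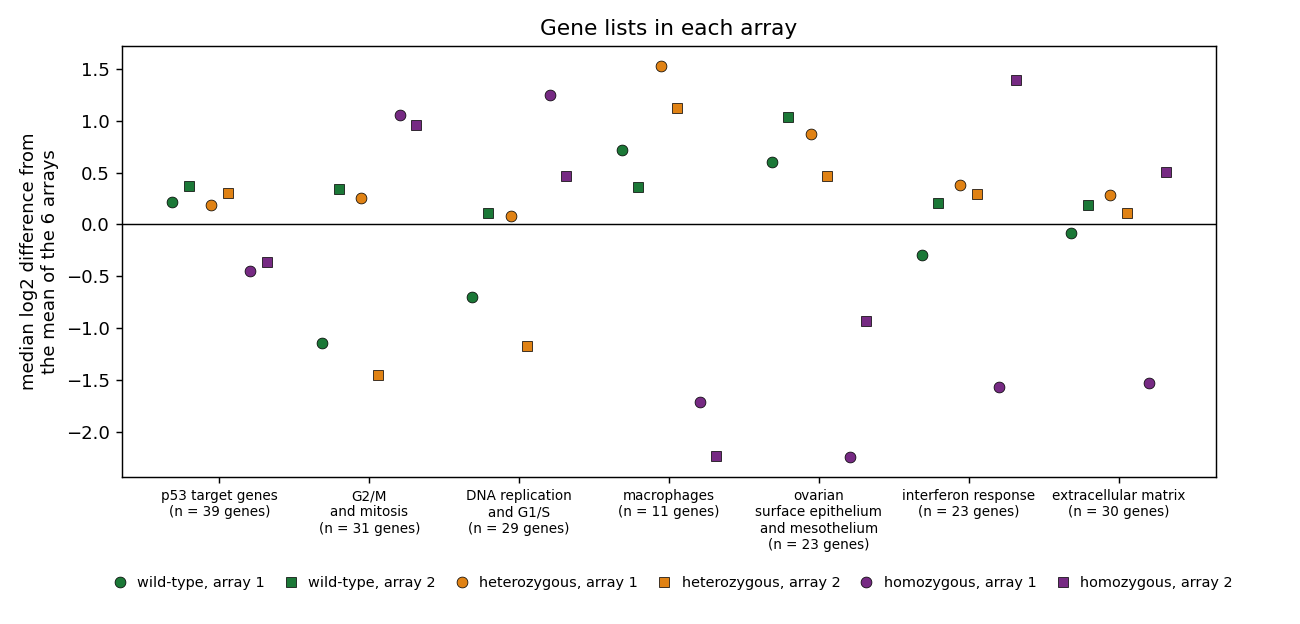
Median log2 difference of each array from the mean of the 6 arrays (vertical axis) over the members of 7 fixed gene lists, with circles for array 1 and squares for array 2 of each group. Mitosis genes differ by 1.496 between the wild-type arrays and by 1.69 between the heterozygous arrays, and interferon genes by 2.98 between the homozygous arrays.

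Position of heterozygous cells between the others. Of the 291 genes called between homozygous and wild-type cells, 289 had a heterozygous mean nearer to wild-type than to homozygous cells, and 168 had it between the 2. A heterozygous mean that differed from wild-type only by noise would also lie between the 2 for many genes. The share by chance was not computed, so the 168 do not show an intermediate level. The 289 follow largely from choosing genes that changed at least 2-fold between homozygous and wild-type cells. Heterozygous minus wild-type changes had an SD of only 0.34 over all tested genes. The test of the heterozygous cells against the midpoint called 0 genes by limma, with 1352 at an unadjusted p under 0.05 and a smallest adjusted p of 0.158. Without homozygous array 1 this count was 117 and without array 2 it was 1079. The log2 fold changes of heterozygous and of homozygous against wild-type cells correlated across genes at a Pearson r of 0.0383, with a covariance of 0.0164; genes are not independent replicates. Unchanged groups sharing the wild-type arrays gave a mean r of 0.4995 and a covariance of 0.135 with the fitted spread, and 0.300 and 0.0598 with a spread scaled to each group, both above the observed values. These draws took the arrays as independent and the homozygous cells as unchanged. In the data wild-type array 2 and heterozygous array 1 lay close together and homozygous cells differed, each of which can lower r. The gap therefore does not show how the heterozygous and homozygous changes relate. The observed r depends on single arrays. It was 0.32 without wild-type array 2, 0.21 without heterozygous array 2, -0.09 without heterozygous array 1 and 0.25 with no filter. The simulation was not repeated for these, so 0.32 cannot be set against 0.300, which holds for 2 wild-type arrays. The 2 wild-type arrays were not split, since each part would hold a single array.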

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

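The offset, the raised signals, the crossed numbers, the removal of both close arrays and the spread differing between groups were chosen after the data were seen. No gene was called between heterozygous and wild-type cells under any alternative. Over the named genes and lists that passed, 938 gene values kept their direction and their call under an alternative and 866 kept only the direction; for lists the numbers were 497 and 86. None of these reversed.

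The count of genes called between homozygous and wild-type cells, 291, was 568 with an intensity trend and robust spread, 1484 at an adjusted p under 0.10, 804 with the offset of 32 and 686 with signals raised to background. It was 194 with a spread differing between groups and 190 with the mean of all probe sets. It was 0 with no filter, which adds dim genes to those tested, and 0 with only the 2 groups compared. It was 0 without both close arrays. The count between homozygous and heterozygous cells, 446, was 1871 at an adjusted p under 0.10, 877 with the offset, 809 with raised signals, 293 with a spread differing between groups, 286 with all probe sets tested, 281 with the mean of probe sets, 17 with no filter, 4 with only the 2 groups compared and 0 without both close arrays. Leaving out 1 array gave between 0 and 2720 calls against wild-type, between 0 and 2913 against heterozygous cells, and between 0 and 1079 against the midpoint. The lone array left in a group was then assumed to vary like the others. The midpoint count was also 3 with the offset, 5 with raised signals and 1 with a spread differing between groups. The cause was not tested further.

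With the replicate number as a block the counts were 0 against wild-type and 19 against heterozygous cells. The labels do not say that the numbers pair the arrays. Deviations of same-numbered arrays from their group means correlated across 5458 genes at -0.416 for wild-type with heterozygous, -0.135 for wild-type with homozygous and 0.179 for heterozygous with homozygous arrays. With the wild-type numbers crossed, the block gave 162 and 348 calls.

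The share of called genes that were higher against wild-type was 15.5%, and 19.3% with median-centred arrays and 16.6% with quantile-normalised arrays. It was 35.3% with the filter at the 60th percentile and 34.8% at an adjusted p under 0.10, and lower with a spread differing between groups (8.25%), the mean of all probe sets (9.47%), the crossed replicate block (11.7%) and all probe sets tested (12.5%). The share thus depends on the filter, though with no filter the median of all genes was -0.17, further under 0 than the -0.09 of the tested genes. How far the filter sets the share was not tested.

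For p53 targets in heterozygous against wild-type cells, the median was -0.20 with no filter (adjusted p 0.131), with an estimated correlation (0.292) and by fry (0.626), and -0.21 without both close arrays (0.321), none of which passed. Leaving out 1 array gave medians from -0.28 to -0.16. In homozygous against wild-type cells the list lost its call with an estimated correlation (-0.62) and without both close arrays (-0.33). In homozygous against heterozygous cells it passed at -0.67 with the intensity trend, by fry and with a spread differing between groups, at -0.42 with the mean of probe sets and at -0.44 with median-centred arrays, and leaving out 1 array gave from -0.68 to -0.43. The cause was not tested.

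Against wild-type cells these medians moved by over 1.5 times and kept their call: epithelial junctions to -0.56 with the mean of all probe sets and -0.95 with the offset, cholesterol synthesis to -0.38, hypoxia to -0.41 and ribosomal proteins to 0.50 with median-centred arrays. Without both close arrays the junction list lost its call against wild-type (-1.57) and heterozygous cells (-1.18), as the cholesterol list did against the latter (-0.61).

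The correlation of the heterozygous and homozygous fold changes against wild-type was 0.25 with no filter, and leaving out 1 array gave from -0.0863 (without heterozygous array 1) to 0.32 (without wild-type array 2), 0.21 without heterozygous array 2. The cause was not tested.

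Lists that did not pass reversed direction, now passing, as single arrays were left out. Heterozygous against wild-type cells had medians of -0.12 for ribosomal proteins without wild-type array 1, and without wild-type array 2 of 0.62 for mitosis and 0.33 for DNA repair. Without heterozygous array 2 they were 0.71 for mitosis, 0.41 for DNA replication and 0.22 for DNA repair. The opposite ends were -1.03, -0.84 and -0.32 for these 3 lists without heterozygous array 1, and 0.23 for ribosomal proteins without wild-type array 2. Interferon genes had a median of 1.13 against heterozygous cells without homozygous array 1 and of -2.26 without array 2. Without homozygous array 2 the medians against wild-type cells were -1.49 for interferon genes and -1.47 for extracellular matrix, and without array 1 they were 1.69 and 0.44. The arrays of a group differ here, so the median follows the array kept.

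Raising signals to background kept the direction and call of each list that passed.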

Other observations

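All tests on the close arrays and on the macrophage genes were chosen only after the results were seen, as was the ribosome biogenesis list, which leaves out the members already seen among called genes.

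The homozygous arrays differed by over 2-fold at 2290 genes, 1601 higher in array 2 and 689 higher in array 1, against 951 genes in the wild-type pair and 768 in the heterozygous pair. Interferon response genes lay higher in array 2 by a median of 2.98 on the log2 scale, granulosa and theca genes by 2.24, extracellular matrix genes by 1.84 and mesenchymal genes by 1.18, while stem cell markers had a median of -1.21 and DNA replication genes of -0.69. Usp18, which removes the ubiquitin-like protein ISG15, had signals of 55.2 in array 1 and 2255 in array 2, and Rtp4 of 51.8 and 2192. Dcn, the matrix proteoglycan decorin, had signals of 865 and 15441, and Col3a1, a fibrillar collagen, of 255 and 31824. Calcrl, an adrenomedullin receptor, was brighter in array 1, at 3286 against 17.4, as was Emb, at 7555 against 51.4. These genes were chosen after their values were seen, and no biological explanation was tested, since both labels give the same genotype and age.

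Ribosome biogenesis genes, which assemble ribosomes in the nucleolus, may be raised together in the homozygous cells. Of 63 genes in a list chosen after the calls were seen, 62 were tested and 62 of 62 were higher than in wild-type cells, with a median of 1.28 and 0 called singly by limma. Members already seen among called genes were left out, so the 0 follows in part from that choice. The same arrays gave the theme and the test, which is therefore not independent support. The median against wild-type cells was 1.51 in homozygous array 1 and 0.99 in array 2. Camera at the preset correlation gave p = 5.8586e-25, the test with an estimated correlation p = 0.0739 and fry p = 0.00635 by limma. Against heterozygous cells 8 rose, with a median of 1.30, and between heterozygous and wild-type cells the median was -0.03 with 22 positive. Lists of mitosis and replication lay higher in the same arrays, so the shift is not specific to this list, and age stays an open explanation.

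Wild-type array 2 and heterozygous array 1 were the closest of the 15 pairs, with 143 genes over 2-fold apart. The p53 targets had a median difference of -0.28406, outside the -0.09 to 0.08 of random lists matched on brightness, with Cdkn1a at -0.77. Other lists lay outside their ranges too, among them macrophages (1.19), hypoxia (0.20) and NRF2 genes (-0.18). Others, such as mitosis (-0.06), lay within theirs. Genes of a list can vary together more than those of random lists, so these ranges may be too narrow. The differences therefore argue only weakly against the same sample under 2 labels. A shared labelling batch cannot be told apart from chance closeness, since the pair ranked 3 of 15 by spiked controls with an SD of 0.158 against a lowest of 0.146. A shared growth state may contribute, as the median of the mitosis genes was higher in each of these arrays than in the other array of its group, by 1.4956 in the wild-type and 1.69 in the heterozygous pair. Without the mitosis, replication and repair lists the pair was still the closest (SD 0.316, next 0.539). That removal kept 10831 of 10916 genes, so it could hardly move the SD. It cannot decide how much of the closeness a growth state explains.

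Fewer macrophages in the homozygous cultures and a lower level of these genes within macrophages cannot be told apart here. Of 18 list members above background in both wild-type arrays, 15, or 83.333%, had both homozygous arrays below both wild-type arrays, but this share restates the fall and would follow from either. Lyz1, Lyz2 and Ctss had wild-type means of 1256, 590 and 560 and lay under background in both homozygous arrays. The members did not move alike, with Csf1r at 488 in homozygous array 2 against 770 and 600 in the wild-type arrays, and, in homozygous array 1, Cd14 at 222 and Laptm5 at 215, above all wild-type values. The age of the animals stays open as well.

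Age could not be separated from homozygosity. Along a straight line through the heterozygous arrays of 9 and 12 weeks, age predicted a median of 2.2905% of the change of the 291 called genes (95% bootstrap interval over genes -0.194 to 5.85). The difference between those arrays also enters the spread by which genes were called, which favours genes where it is small. The interval resamples genes and does not measure the uncertainty of the line. With 1 array at each age this line also carries the difference between those arrays, so an effect of age on the called genes cannot be told apart from one of genotype.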
